A study of Mus musculus with 18 samples.

How the data were processed

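RNA sequencing counts of 18 libraries were analysed, 3 from each of 6 groups. Per the labels, gp38+ (podoplanin-bearing) stromal cells were sorted by flow cytometry from salivary glands of Balb/c mice that were uninfected (hour 0) or had received a replication-defective adenovirus 5 through the cannulated submandibular duct 3 hours, 1 day, 2 days, 8 days or 23 days earlier. The deposited values are raw counts per Ensembl gene. Per the submitters' processing notes, reads were checked with FastQC, aligned to mm10 with STAR and counted with Subread, and DESeq2 was used for differential expression. Those notes give no version, annotation release, strand setting or handling of reads that map to several places.

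Gene names, exon lengths and positions were taken from GENCODE release M21 on GRCm38 (mm10). Of 55401 gene identifiers 55141 matched it, and the other 260 held 0.0241% of all counts. Total counts per library ran from 4398234 to 15234431, with a median of 10227904. Intervals cover counting error only, since reads without molecular identifiers are not independent molecules.

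All 18 libraries were fitted together with edgeR 4.0.16 (R 4.3.3) by the quasi-likelihood method. The filter was filterByExpr with a minimum count of 10 and a minimum total of 15, which left 27525 genes, and scaling was by TMM. Each infected group was compared with hour 0 and each time point with the one before it, and an F test asked for any change over the 6 groups. Genes with a Benjamini-Hochberg adjusted p under 0.05 within a contrast are said to have risen or fallen. CPM values are scaled by TMM. Folds against a group at 0 counts are lower bounds from a floor of 3 counts over the group, and for 1 to 3 counts the ratio is given with its exact 95% interval for counts.

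A group of 29 gene lists was tested with camera (limma 3.58.1) on log2 CPM with a prior count of 2 and a preset correlation of 0.01, adjusted over 174 tests in 6 contrasts, namely the infected groups against hour 0 and day 23 against day 8. The lists hold immediate-early genes, heat-shock genes, inflammatory cytokines and NF-kB targets, type I interferon-stimulated genes, interferon-gamma-responsive genes, MHC class I and class II antigen presentation, lymphoid stromal and immunofibroblast genes, H3K27 methylation writers and erasers, cell cycle genes, extracellular matrix genes, matrix-remodelling enzymes and inhibitors, contractile and myofibroblast genes, resting fibroblast genes, glycolysis, cholesterol synthesis and complement genes. Markers of other cells form the rest: acinar and duct secretory, epithelial and myoepithelial, blood endothelial, lymphatic endothelial, mural, T and NK, B and plasma, macrophage with monocyte and dendritic, neutrophil, glial, adipocyte and erythroid genes. Sex-linked genes served as a check of the samples. Camera compares the members of a list with all other genes tested, so a call is relative to those genes. Members that pass the gene test are counted over all genes tested and adjusted over the list alone.

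Named genes follow a rule. For each infected group against hour 0 they are the 8 largest rises and 8 largest falls with an adjusted p under 0.05, a mean CPM of at least 10 in the higher group and no overlap between the groups' libraries, which chance gives for 10% of genes at 3 against 3. Predicted gene models, clones and immunoglobulin or T cell receptor segments were left out of these. To them were added up to 3 members of each list, and always Kdm6b, Kdm6a, Ezh2, Pdpn, Pdgfra, Cxcl13, Ccl19 and Il6. Steps between time points took 4 rises and 4 falls. The groups, contrasts, tests, lists, naming rule and a set of other settings were fixed before the data were examined.

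The shares of counts on mitochondrial genes and on the 10 most abundant genes were compared with hour 0 by two-sided exact permutation tests (scipy 1.17.1), whose smallest possible p at 3 against 3 is 0.1, adjusted over 10 tests. Counts on 1499 sensory receptor genes (olfactory, vomeronasal and taste), which stromal cells are not known to express, served as a measure of background.

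The other settings fixed beforehand were DESeq2 size factors in edgeR, no filter on low counts, a filter of 5 CPM in 3 libraries, DESeq2 1.42.0, limma-voom, a fit of only the 2 groups compared, leaving out each replicate in turn, and camera with a correlation estimated per list. For the test over 6 groups DESeq2 used its likelihood-ratio test where the plan named the Wald test, which cannot test 5 coefficients at once. After seeing the data, 5 alternatives were added: scaling by library totals alone, a fit without day 2, a fit of only 1 set of 9 libraries (hour 0, day 1 and day 2, or hour 3, day 8 and day 23), and 2 subtractions of background. The first subtraction used 1 rate per kb and library from the receptor genes. It was replaced, after its counts had been seen, because rates in silent genes differed several-fold with GC content. The other estimates the rate in 10 bins of GC content from 5425 protein-coding genes of at least 500 bp of exon with at most 3 counts over the 9 libraries of hour 3, day 8 and day 23, so the rates of those libraries are close to 0 by choice.

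The pipeline was tested on simulated counts drawn from the hour 0 mean of each gene in every group and the real library sizes. They hold no difference between the sets, and the changed genes were taken from the better-counted ones. Far fewer genes were changed than were called in the real contrasts, so the shares recovered need not carry over to those. Of genes changed 4-fold, between 78.8% and 84.8% were recovered in the 5 simulated comparisons of 27525 genes, of those changed 2-fold between 23.9% and 35.8%, and of those changed 1.5-fold between 1.49% and 5.97%. Between 0% and 5.33% of calls were false, and 0 of 28 lists left unmoved were called. Each gene was drawn independently, so the 0 of 28 does not bear on lists whose members vary together. Python 3.11.15, pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9 were used for tables and plots.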

Results

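Gene expression was measured in gp38+ stromal cells, the fibroblast-rich fraction that carries podoplanin, sorted from mouse salivary glands. The 18 libraries form 6 groups of 3, each library from a mouse of its own: uninfected glands (hour 0, replicates 10 to 12), and glands 3 hours (replicates 4 to 6), 1 day (13 to 15), 2 days (16 to 18), 8 days (1 to 3) and 23 days (7 to 9) after cannulation with replication-defective adenovirus 5. Total counts were 8542729, 7153873 and 10619144 at hour 0, then 14881470, 13886173 and 14739933 at hour 3, and 9836665, 8734113 and 10635986 at day 1. At day 2 they were 4398234, 5345881 and 6313619, at day 8 they were 12033146, 14041925 and 15234431, and at day 23 they were 6017781, 14565048 and 4585868. No group was cannulated without virus, so every contrast with hour 0 holds the procedure and the virus together.

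The libraries divide into sets that the labels do not name, though the replicate numbers follow them. Replicates 1 to 9 are the libraries of hour 3, day 8 and day 23, and replicates 10 to 18 those of hour 0, day 1 and day 2. At the smallest depth the 9 libraries of hour 0, day 1 and day 2 detected 25288 to 41114 genes, and the 9 of hour 3, day 8 and day 23 detected 16456 to 19327. Counts on sensory receptor genes, per kb of exon and 10M nuclear counts, were 1.42 ± 0.382 at hour 0, 0.798 ± 0.306 at day 1 and 3.24 ± 0.0995 at day 2, against 0.0495 ± 0.0106, 0.0222 ± 0.00167 and 0.0212 ± 0.00699 at hour 3, day 8 and day 23 (mean ± SD, n = 3). Set and time cannot be told apart in the contrasts of hour 3, day 8 and day 23 with hour 0, of day 1 with hour 3, and of day 8 with day 2. Within the sets lie day 1 and day 2 against hour 0, day 2 against day 1, and day 23 against day 8. Day 2 stood apart within its set, with 39801 to 41114 genes detected at the smallest depth. Hour 0 had 28294 to 31903 and day 1 had 25288 to 29477. Time and level of background cannot be told apart in the contrasts of day 2 either.

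**Figure D1:**
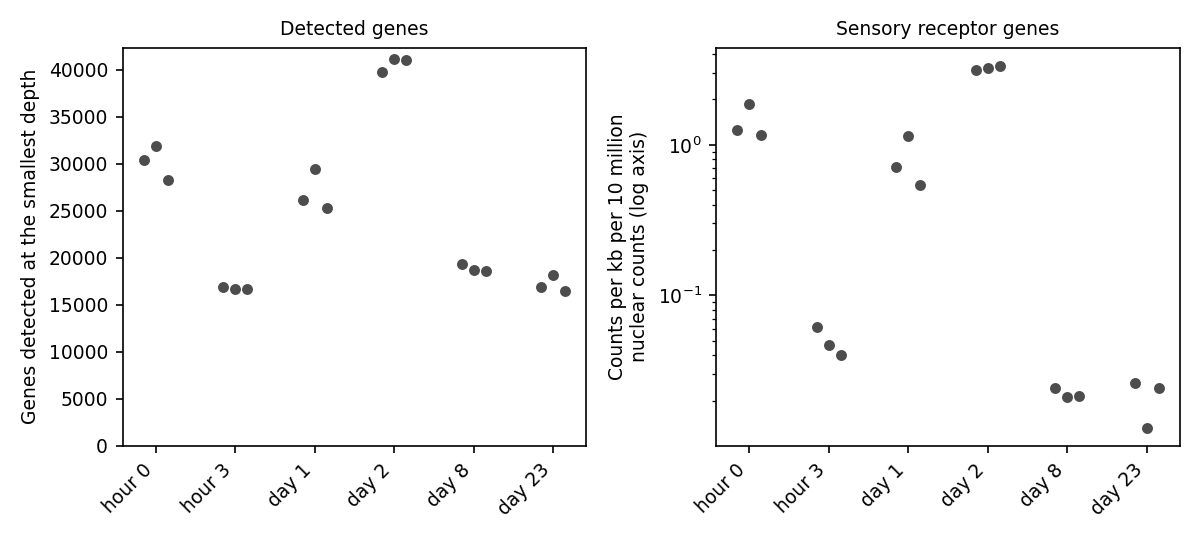
Genes detected at the smallest depth (left, number of genes) and counts on sensory receptor genes per kb per 10M nuclear counts (right, log axis), 1 point per library, by group. The libraries of hour 0, day 1 and day 2 lie at 25288 genes or more and at 0.541 receptor counts or more, and the others at 19327 genes or fewer and at 0.0612 or fewer.

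Mucl2, which encodes a salivary mucin-like protein (ENSMUSG00000036925, chromosome 15, 103895855 to 103899312), took a mean of 5.64% of counts at hour 0, 0.0753% at day 2 and 12.7% at day 23. The 10 most abundant genes took 19.1% ± 2.26 of counts at hour 0, 22.2% ± 1.71 at hour 3, 11.1% ± 1.86 at day 1, 13.4% ± 0.957 at day 2, 29.3% ± 5.71 at day 8 and 29.9% ± 5.28 at day 23 (SD, n = 3). Mitochondrial genes took 6.45% ± 0.847, 7.25% ± 1.52, 3.84% ± 0.658, 5.84% ± 0.505, 14.6% ± 1.56 and 9.74% ± 1.85 in the same order. The lowest exact permutation p against hour 0 was 0.1 (two-sided, the smallest that 3 against 3 allows; 0.143 adjusted over 10 tests), so none of these shares could pass 0.05. Of the 5 sex-linked genes, the 4 on the Y chromosome (Ddx3y, Eif2s3y, Kdm5d and Uty) had 0 counts in all 18 libraries and were not tested. Xist, the RNA gene of X inactivation, took 0.0302% to 0.0926% of counts in them, as in cells of female mice.

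Over the 6 groups 23092 of 27525 genes changed (edgeR F test, adjusted p under 0.05). Scaling bears on directions: with library totals alone in place of TMM, the median shift in log2 fold change over all genes was -1.15 for hour 3 against hour 0, 0.37 for day 2, -0.39 for day 8, -0.44 for day 23, 1.25 for day 1 against hour 3, 0.27 for day 2 against day 1 and -0.76 for day 8 against day 2. DESeq2 size factors shifted it by 0.207, -0.128 and -0.121 for day 2, day 8 and day 23 against hour 0, by 0.209 for day 2 against day 1 and by -0.336 for day 8 against day 2. The share of called genes that were higher moved with library totals from 28.1% to 7.09% at hour 3, from 34.7% to 66.7% at day 2, from 25.5% to 10.3% at day 8 and from 25.1% to 6.05% at day 23. For the steps it moved from 62.1% to 91.8% (hour 3 to day 1), from 51.8% to 77.9% (day 1 to day 2) and from 29.4% to 8.29% (day 2 to day 8).

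Il6, an inflammatory cytokine gene (ENSMUSG00000025746, chromosome 5, 30013114 to 30019981), rose from 22.0 ± 22.0 CPM at hour 0 to 8355 ± 2324 at hour 3 (SD, n = 3; log2 fold change 8.55 ± 0.625 SE, adjusted p = 3.97e-12). The comparison of hour 3 with hour 0 asks which genes respond first to virus and procedure. Kdm6b, the H3K27 demethylase gene named in the series title (ENSMUSG00000018476, chromosome 11, 69398508 to 69413675), rose from 228 ± 22.8 to 2906 ± 56.1 CPM (3.67 ± 0.235, adjusted p = 2.6e-13). Pdpn, which encodes gp38 itself (ENSMUSG00000028583, chromosome 4, 143267431 to 143299564), rose from 60.4 ± 6.09 to 827 ± 100.4 (3.77 ± 0.239, adjusted p = 2.22e-13). The largest rise belonged to Cxcl5, a neutrophil-attracting chemokine (ENSMUSG00000029371, chromosome 5, 90759360 to 90761624), at 9.32 ± 0.466. Next came Cxcl2, a chemokine of the same kind (9.01), and Ch25h, which makes the B cell attractant precursor 25-hydroxycholesterol (8.96). Ptx3, a secreted pattern receptor gene, rose by 8.78, followed by the monocyte chemokine Ccl2 (8.53), the protease inhibitor Tfpi2 (8.45) and the cytokine Lif (8.31). Kdm6a, the paralog of Kdm6b, passed no test (0.09, adjusted p = 0.661), but fell by 1.08 with library totals alone (adjusted p = 2.47e-05). Pdgfra, which encodes platelet-derived growth factor receptor alpha, a fibroblast marker (ENSMUSG00000029231, chromosome 5, 75152292 to 75198215), was at 0.40 (adjusted p = 0.0506), with -0.78 under library totals. The B cell chemokine gene Cxcl13 rose by 1.18 (adjusted p = 0.00238), and with library totals its change was 0.00 (adjusted p = 1).

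In all, 16503 genes changed at hour 3, with 4638 higher and 11865 lower. With the stricter filter 9329 of 14147 changed, 4037 of them higher and 5292 lower. With library totals 1489 were higher and 19500 lower, and 681 of the genes called both ways had the opposite sign. The largest falls were of genes at 63.0 CPM or less in hour 0: Irx4 (ratio 237, interval 42.3 to 9400), Mroh2a, Cacna1e, Cbfa2t3, Slx1b, Csmd2, Ryr3 and Ttn, a muscle gene (-5.79 ± 0.482), all of which still passed after either subtraction of background. This contrast crosses the sets, and 7074 of the 11865 lower genes lie outside the stricter filter. The receptor-gene subtraction ignores GC content, and the other rests on genes chosen as almost absent at hour 3. Passing them does not tell a response from background.

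Every measured inflammatory cytokine and NF-kB target rose at hour 3 (27 of 27, and 27 adjusted over the list alone, camera adjusted p = 2.35e-28, adjusted p = 0.0315 with an estimated correlation). With library totals 26 still rose. Type I interferon-stimulated genes rose in 24 of 26 (24 adjusted over the list alone, 8.24e-22, adjusted p = 0.0495 with an estimated correlation). Among them were Ifit1 (5.71), which blocks viral translation, and Rsad2 (5.57), an antiviral enzyme. With library totals 22 rose and 3 fell. Of 21 lymphoid stromal and immunofibroblast genes 11 rose and 2 fell (12 and 2 adjusted over the list alone, 1.24e-06, adjusted p = 0.0223 with an estimated correlation). Matrix-remodelling enzymes and inhibitors rose in 15 of 17 and fell in 1 (15 and 1 adjusted over the list alone, 4.65e-11, adjusted p = 0.0697 with an estimated correlation). Timp1, a metalloproteinase inhibitor gene, rose by 6.76.

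The calls of the other lists at hour 3 ended with an estimated correlation. Interferon-gamma-responsive genes rose in 17 of 20 and fell in 2 (17 and 2 adjusted over the list alone, camera adjusted p = 9.48e-11, adjusted p = 0.144 with an estimated correlation). The checkpoint ligand gene Cd274 rose by 6.79 and the T cell chemokine Cxcl10 by 6.75. MHC class I genes rose in 13 of 15 (13 adjusted over the list alone, 1.63e-08, adjusted p = 0.157 with an estimated correlation). Neutrophil genes, S100a9 among them, rose in 5 of 7 with 1 falling (5 and 1 adjusted over the list alone, 0.00163, adjusted p = 0.0814 with an estimated correlation). Extracellular matrix genes rose in 21 of 24 and fell in 1 (21 and 1 adjusted over the list alone, 2.5e-10, adjusted p = 0.144 with an estimated correlation) with a median of 1.12 that was -0.06 under library totals. The collagen cross-linking enzyme gene Lox rose by 6.53. Resting fibroblast genes had 12 rises and 1 fall among 20 (14 and 1 adjusted over the list alone, 4.99e-05, adjusted p = 0.172 with an estimated correlation), and 1 rise and 9 falls under library totals, where their median of 0.58 became -0.59. Glycolysis genes had 11 rises and 1 fall among 15 (11 and 1 adjusted over the list alone, 2.82e-07, adjusted p = 0.0803 with an estimated correlation) with a median of 0.94 that was -0.24 under library totals. Hk2, a hexokinase gene, rose by 6.41. Complement genes rose in 8 of 11 (8 adjusted over the list alone, 6.4e-05, adjusted p = 0.104 with an estimated correlation), but under library totals 1 rose and 2 fell.

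Immediate-early genes split at hour 3, with 10 rises and 6 falls among 20 (10 and 6 adjusted over the list alone, camera adjusted p = 0.000231, adjusted p = 0.365 with an estimated correlation). The transcription factor genes Fosl1 (5.95) and Myc (5.18) rose, and the list's median of 0.60 was -0.57 under library totals. Heat-shock genes had 7 rises and 3 falls among 12 (7 and 3 adjusted over the list alone, 0.000978, adjusted p = 0.291 with an estimated correlation). H3K27 methylation writers and erasers had 7 rises and 2 falls among 12 (7 and 2 adjusted over the list alone, 0.00164, adjusted p = 0.104 with an estimated correlation), with a median of 0.68 that was -0.49 under library totals. Secretory genes had 11 rises and 4 falls among 21 (12 and 4 adjusted over the list alone, 0.00779, adjusted p = 0.456 with an estimated correlation), with a median of 1.13 that was -0.03 under library totals. With the stricter filter the calls of these 4 lists ended (adjusted p = 0.0725, 0.0656, 0.104 and 0.11). With only the 2 groups compared the last 3 ended too (0.0522, 0.0736 and 0.0781), as did the H3K27 list with library totals (0.176) and the secretory list after subtraction of estimated background (0.0562). Some lists without a call mostly fell, while genes outside the stricter filter had a median of -4.392. Rises and falls were 2 and 8 of 12 for contractile (camera adjusted p = 0.768, pointing up) and 2 and 13 of 25 for cell cycle genes (0.756). They were 0 and 9 of 14 for T and NK (0.285) and 0 and 6 of 11 for B and plasma cell genes (0.186). Adipocyte genes had 0 and 5 of 7 (0.263) and blood endothelial genes 1 and 6 of 11 (0.608).

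**Figure D2:**
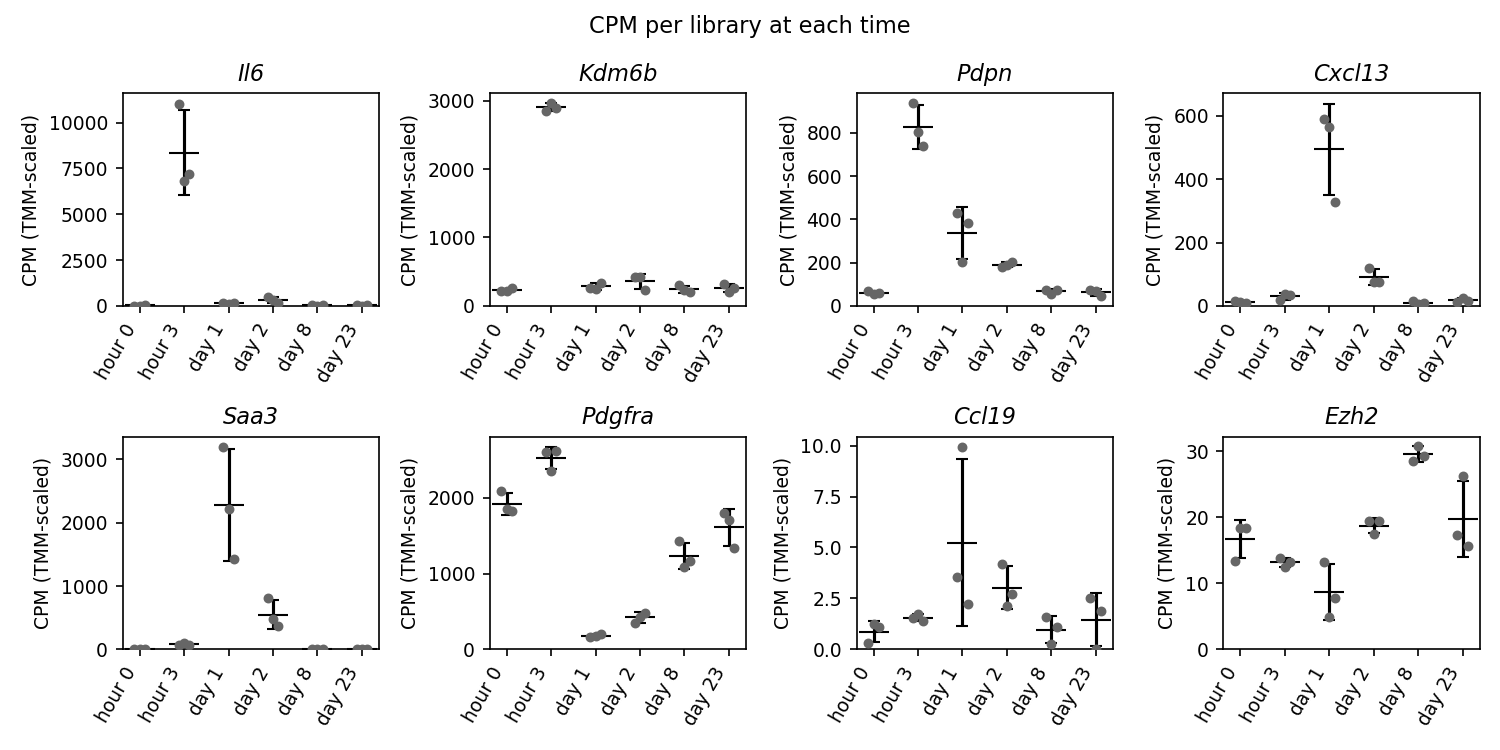
CPM (TMM-scaled, linear axes from 0) of 8 genes by time, with 1 point per library and the mean ± SD of 3 libraries as bars. Il6, Kdm6b and Pdpn peaked at hour 3 (means of 8355, 2906 and 827 CPM), Cxcl13 and Saa3 at day 1 (494 and 2278 CPM), and Pdgfra was lowest at day 1 (182 CPM).

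Saa3, an acute-phase protein gene (ENSMUSG00000040026, chromosome 7, 46711998 to 46715700), rose from 1.49 ± 1.14 CPM at hour 0 to 2278 ± 887 at day 1 (log2 fold change 10.50 ± 0.518, adjusted p = 5.24e-15), the largest rise of the named genes there. The comparison of day 1 with hour 0 asks what state follows the first hours. It lies within a set of libraries, though estimated background was 1.66% of counts at day 1 and 3.53% at hour 0. Cxcl13 (ENSMUSG00000023078, chromosome 5, 95956951 to 95961068), which draws B cells, rose from 13.4 ± 3.27 to 494 ± 145 CPM (5.21 ± 0.34, adjusted p = 1.02e-12), and Pdgfra fell from 1922 ± 145 to 182 ± 23.6 (-3.40 ± 0.191, adjusted p = 5.65e-14). The T cell chemokine gene Ccl5 was higher at a ratio of 698 (interval 193 to 5770). The iron-binding protein gene Lcn2 rose by 8.35, as did the interferon-induced GTPase gene Tgtp1 by 8.07, which shares sequence with a close paralog. Of the named genes, the largest falls were of Klk1b9, a kallikrein gene with close paralogs (ratio 204, 69.3 to 990), Myh11, a smooth muscle myosin (-7.39), the salivary protein gene Smgc (-6.81), a further kallikrein, Klk1b11 (-6.69), the growth factor gene Alkal2 (-6.56), Ppp1r1b, a phosphatase inhibitor gene (-5.95), and the basement membrane collagen Col15a1 (-5.70). Il6 was still raised (2.56, adjusted p = 0.000164), as was Pdpn (2.48, adjusted p = 7.76e-10), whereas Kdm6b passed no test (0.31, adjusted p = 0.319). Ccl19, a chemokine of T cell zones, rose by 2.57 (adjusted p = 0.0317), but not without replicate 10, 12 or 14 (adjusted p = 0.116, 0.0579 and 0.177), with limma-voom (0.0551) or without the day 2 libraries (0.0545). Ezh2, the H3K27 methyltransferase gene, fell by 0.95 (adjusted p = 0.0117), but not without replicate 14 or 15 (adjusted p = 0.078 and 0.0558), with no filter (0.0555), with only the 2 groups compared (0.089) or in a fit of only the set of hour 0, day 1 and day 2 (0.0574).

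At day 1 a total of 6193 genes changed, 2662 higher (43.0%) and 3531 lower. The majority turned with no filter (54.0% higher), with only the 2 groups compared (53.8%), with the stricter filter (50.1%) and in a fit of only the set of hour 0, day 1 and day 2 (51.3%), and limma-voom gave 35.7%. All 26 type I interferon-stimulated genes rose (26 adjusted over the list alone, camera adjusted p = 2.17e-38, adjusted p = 0.0185 with an estimated correlation). Oas3, a sensor of viral RNA, rose by 6.13. All 27 inflammatory genes (27 adjusted over the list alone, 1.24e-23, adjusted p = 0.0451 with an estimated correlation) rose. So did all 15 MHC class I genes (15 adjusted over the list alone, 1.55e-20, adjusted p = 0.0495 with an estimated correlation), their activator Nlrc5 by 3.82. Interferon-gamma-responsive genes rose in 18 of 20 (18 adjusted over the list alone, 8.24e-22, adjusted p = 0.0588 with an estimated correlation). Glycolysis genes rose in 13 of 15 (14 adjusted over the list alone, 9.28e-13, adjusted p = 0.0343 with an estimated correlation). Heat-shock genes rose in 11 of 12 (12 adjusted over the list alone, 3.81e-11, adjusted p = 0.0701 with an estimated correlation). Lymphoid stromal and immunofibroblast genes rose in 9 of 21 and fell in 4 (9 and 4 adjusted over the list alone, 0.0184, adjusted p = 0.145 with an estimated correlation). That call ended with the stricter filter (0.187) and with only the 2 groups compared (0.0534). Complement genes rose in 6 of 11 and fell in 1 (6 and 2 adjusted over the list alone, 0.00535, adjusted p = 0.221 with an estimated correlation). With the stricter filter it ended (0.0758).

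Resting fibroblast genes fell at day 1 in 15 of 20 and rose in 3 (15 and 3 adjusted over the list alone, camera adjusted p = 2.96e-05, adjusted p = 0.168 with an estimated correlation). Clec3b, a plasminogen-binding lectin gene, was at -3.60. Extracellular matrix genes fell in 15 of 24 and rose in 3 (15 and 3 adjusted over the list alone, 0.000526, adjusted p = 0.382 with an estimated correlation). Tnc, a matrix protein of injured tissue, rose by 4.13. All 8 glial genes fell (8 adjusted over the list alone, 6.22e-06, adjusted p = 0.0315 with an estimated correlation), the neurotrophic receptor gene Gfra3 at -4.25. Mural cell genes fell in 5 of 8 and rose in 1 (5 and 1 adjusted over the list alone, 0.0184, adjusted p = 0.195 with an estimated correlation), with the pericyte channel gene Abcc9 at -5.10. The call ended without replicate 12 or 14 (adjusted p = 0.0514 and 0.0624). Contractile genes fell in 8 of 12 and rose in 3 (8 and 3 adjusted over the list alone, 0.0343, adjusted p = 0.487 with an estimated correlation). Their call ended with the stricter filter (adjusted p = 0.0724) and without replicate 10 or 14 (0.0897 and 0.0903). Secretory genes fell in 14 of 21 and rose in 1 (14 and 1 adjusted over the list alone, 0.000285, adjusted p = 0.309 with an estimated correlation). Their median was -3.46, or -2.98 with the member at 0 counts set at its bound. Cholesterol synthesis genes fell in 7 of 16 (7 adjusted over the list alone, 0.00768, adjusted p = 0.318 with an estimated correlation).

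Scgb1b27, a secretoglobin gene of salivary secretion with close paralogs, fell from 4834 ± 1883 CPM at hour 0 to 12.4 ± 13.8 at day 2 (log2 fold change -8.65 ± 0.676, adjusted p = 9.65e-11). The comparison of day 2 with hour 0 asks which of the day 1 changes were still present. It lies within the same set, with an estimated background of 10.2% of counts at day 2 and 3.53% at hour 0, so it holds time and background together. Mucl2 fell from 47650 ± 18630 to 495 ± 468 CPM (-6.59 ± 0.578, adjusted p = 8.8e-10), and the salivary protein gene Prol1 by 6.81. The secretoglobins Scgb2b26 and Scgb2b27, paralogs as well, were at -8.39 and -8.32 and Crisp3 at -7.22. Saa3 (8.45), Cxcl5 (7.40), Lcn2 (5.87), Timp1 (5.75) and the phosphate hormone gene Fgf23 (5.81) rose, and Ccl5 was higher at a ratio of 358 (98.6 to 2960). Cxcl13 rose by 2.77 (adjusted p = 7.94e-08) and Il6 by 3.82, and Pdgfra fell by 2.19. Kdm6b rose by 0.65 (adjusted p = 0.0354), a call that ended with limma-voom (0.0544), with only the 2 groups compared (0.073) and without replicate 10, 11, 16 or 17 (0.12, 0.111, 0.213 and 0.201). In a fit of only the set of hour 0, day 1 and day 2 it ended too (0.0697).

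At day 2 a total of 4061 genes changed, 1409 higher (34.7%) and 2652 lower. The share higher was 52.7% with DESeq2 size factors, 52.3% with DESeq2, 59.6% with limma-voom and 30.3% with no filter. Type I interferon-stimulated genes rose in 25 of 26 (26 adjusted over the list alone, camera adjusted p = 3.34e-24, adjusted p = 0.045 with an estimated correlation). Resting fibroblast genes fell in 15 of 20 and rose in 2 (15 and 2 adjusted over the list alone, 1.51e-12, adjusted p = 0.0496 with an estimated correlation), with Gsn, an actin-severing protein gene, at -4.13. Inflammatory genes rose in 23 of 27 (26 adjusted over the list alone, 4.74e-13, adjusted p = 0.088 with an estimated correlation). Cell cycle genes rose in 12 of 25 (16 adjusted over the list alone, 0.000477, adjusted p = 0.076 with an estimated correlation), with the nucleotide reductase gene Rrm2 at 2.43. Secretory genes fell in 11 of 21 and rose in 1 (13 and 1 adjusted over the list alone, 4.44e-08, adjusted p = 0.145 with an estimated correlation). Epithelial and myoepithelial genes fell in 9 of 14 (13 adjusted over the list alone, 6.88e-08, adjusted p = 0.0957 with an estimated correlation), the adhesion gene Cdh1 at -2.05.

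Other calls of day 1 were also present at day 2. Interferon-gamma-responsive genes rose in 18 of 20 (18 adjusted over the list alone, camera adjusted p = 5.62e-12, adjusted p = 0.117 with an estimated correlation). MHC class I genes rose in 14 of 15 (14 adjusted over the list alone, 1.36e-07, adjusted p = 0.172 with an estimated correlation). Glycolysis genes rose in 9 of 15 (10 adjusted over the list alone, 0.000921, adjusted p = 0.201 with an estimated correlation). Extracellular matrix genes fell in 12 of 24 and rose in 4 (12 and 4 adjusted over the list alone, 1.19e-05, adjusted p = 0.291 with an estimated correlation). Contractile genes fell in 7 of 12 and rose in 2 (7 and 3 adjusted over the list alone, 0.00017, adjusted p = 0.214 with an estimated correlation). Cholesterol synthesis genes fell in 6 of 16 (9 adjusted over the list alone, 7.35e-05, adjusted p = 0.157 with an estimated correlation). No call was made at day 2 for 5 lists called at day 1: heat-shock (2 rises and 1 fall, adjusted p = 0.858), glial (1 and 1, 0.735), mural (1 and 2, 0.0931), lymphoid stromal (6 and 3, 0.512) and complement genes (3 and 3, 0.379). Neutrophil genes, not called at day 1 (0.377), rose in 2 of 7 (3 adjusted over the list alone, 0.0343, adjusted p = 0.182 with an estimated correlation). That call ended with only the 2 groups compared (0.0781), without replicate 10, 11, 12 or 16 (0.0553, 0.0699, 0.079 and 0.118), after subtraction of estimated background (0.0684) and with library totals (0.0596).

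Wfdc18, a secreted protease inhibitor gene (ENSMUSG00000000983, chromosome 11, 83709015 to 83711348), rose from 5.18 ± 3.83 CPM at hour 0 to 370 ± 80.0 at day 8 (log2 fold change 6.13 ± 0.476, adjusted p = 5.75e-10). The comparison of day 8 with hour 0 asks what is left or newly present after the first week, and it crosses the sets of libraries. The salivary protein gene Bpifa2 rose by 5.18, the pheromone carrier Mup5 by 5.10, the leucine-rich glycoprotein Lrg1 by 4.99 and the proliferation marker Mki67 by 3.30. Cxcl13 (-0.45, adjusted p = 0.24), Kdm6b (0.09, adjusted p = 0.751), Pdpn (0.18, adjusted p = 0.53) and Ccl19 (0.16, adjusted p = 0.901) passed no test, though Cxcl13 was lower with library totals (-0.83, adjusted p = 0.0306). Pdgfra fell by 0.64 (adjusted p = 0.00611; 0.0545 with no filter). Ezh2 rose by 0.82 (adjusted p = 0.017), which was lost with the stricter filter (0.0518), with library totals (0.18), after subtraction of estimated background (0.0553), without the day 2 libraries (0.0722) and without replicate 10 or 2 (0.0669 and 0.0973).

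At day 8 a total of 12076 genes changed, 3082 higher and 8994 lower, and with the stricter filter 4851 did, 2106 higher and 2745 lower. Leaving out replicate 1, 2 or 3 gave 7954, 7215 and 7204. The largest falls were again of genes at 26.3 CPM or less in hour 0, such as Csmd2 (ratio 372, interval 66.2 to 14700), the calcium channel genes Ryr1 and Ryr3, and Lrp2.

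Cell cycle genes rose in 17 of 25 at day 8 (18 adjusted over the list alone, camera adjusted p = 6.13e-13, adjusted p = 0.00608 with an estimated correlation). MHC class II genes, which present antigen to helper T cells, rose in 6 of 7 (7 adjusted over the list alone, 4.05e-08, adjusted p = 0.076 with an estimated correlation), with the protease Ctss at 4.57 and H2-Eb1 at 4.32. MHC class I genes rose in 15 of 15 (15 adjusted over the list alone, 7.89e-13, adjusted p = 0.0842 with an estimated correlation). Epithelial genes rose in 11 of 14 (11 adjusted over the list alone, 9.87e-12, adjusted p = 0.0588 with an estimated correlation), the keratin gene Krt8 at 3.85 and the tight junction gene Cldn4 at 3.49. Secretory genes rose in 13 of 21 and fell in 2 (13 and 3 adjusted over the list alone, 2.16e-06, adjusted p = 0.187 with an estimated correlation). Macrophage, monocyte and dendritic genes rose in 8 of 14 and fell in 1 (8 and 1 adjusted over the list alone, 1.24e-06, adjusted p = 0.0701 with an estimated correlation), with the lysozyme gene Lyz2 at 3.79.

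Response lists were also called at day 8, relative to all other genes. Genes outside the stricter filter had a median log2 fold change of -3.875 there, against -0.054 in the fit with that filter. At day 23 these medians were -4.563 and -0.034. Interferon-gamma-responsive genes rose in 16 of 20 and fell in 1 (17 and 1 adjusted over the list alone, camera adjusted p = 1.92e-10, adjusted p = 0.145 with an estimated correlation). Type I interferon-stimulated genes rose in 12 of 26 and fell in 1 (12 and 1 adjusted over the list alone, 1.49e-07, adjusted p = 0.182 with an estimated correlation). Inflammatory genes rose in 11 of 27 and fell in 2 (11 and 3 adjusted over the list alone, 7.17e-05, adjusted p = 0.309 with an estimated correlation). Immediate-early genes rose in 10 of 20 (13 adjusted over the list alone, 1.37e-06, adjusted p = 0.243 with an estimated correlation). Glycolysis genes rose in 12 of 15 (12 adjusted over the list alone, 1.4e-07, adjusted p = 0.076 with an estimated correlation). Heat-shock genes rose in 4 of 12 (4 adjusted over the list alone, 0.00154, adjusted p = 0.303 with an estimated correlation). Complement genes rose in 5 of 11 (5 adjusted over the list alone, 0.000746, adjusted p = 0.157 with an estimated correlation). With the stricter filter the last 2 calls ended (0.0849 and 0.0631).

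The stricter filter ended further calls at day 8. Blood endothelial genes rose in 5 of 11 and fell in 1 (7 and 1 adjusted over the list alone, camera adjusted p = 0.00196, adjusted p = 0.24 with an estimated correlation, 0.0752 with the stricter filter). T and NK cell genes rose in 5 of 14 (3 adjusted over the list alone, 0.000285, adjusted p = 0.076 with an estimated correlation, 0.321 with the stricter filter). Erythroid genes rose in 3 of 6 (3 adjusted over the list alone, 0.00261, adjusted p = 0.106 with an estimated correlation, 0.0725 with the stricter filter). Resting fibroblast genes had 12 falls and 2 rises among 20 (12 and 4 adjusted over the list alone) without a call by camera (adjusted p = 0.394), and with the stricter filter the list was called (0.011). H3K27 methylation writers and erasers rose in 5 of 12 (5 adjusted over the list alone, 0.00282, adjusted p = 0.117 with an estimated correlation, 0.143 with the stricter filter), with 1 rise and 1 fall under library totals, where their median of 0.36 was -0.04. Lymphoid stromal genes had 4 rises and 5 falls among 21 (4 and 5 adjusted over the list alone) and were not called (0.224), the test pointing up where median and mean were -0.03 and -0.39. Lymphatic endothelial genes (0 rises and 3 falls of 6, 0 and 4 adjusted over the list alone, 0.662), B and plasma cell genes (0 and 4 of 11, 0 and 4 adjusted over the list alone, 0.4) and adipocyte genes (1 and 3 of 7, 2 and 3 adjusted over the list alone, 0.973) were not called.

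Dcpp1, a demilune and parotid secretory protein gene with close paralogs, rose from 0.221 ± 0.382 CPM at hour 0 to 62.85 ± 42.9 at day 23 (log2 fold change 7.90 ± 0.935, adjusted p = 1.57e-06). Its SD at hour 0 is above the mean, so the size of this fold is loose. The comparison of day 23 with hour 0 asks what lasts past 3 weeks, and it also crosses the sets. Wfdc18 rose by 5.46, Mup5 by 4.72, the small nucleolar RNA gene Snora21 by 5.25 and the class II gene H2-Ab1 by 3.66. Fdps, a cholesterol synthesis enzyme gene (ENSMUSG00000059743, chromosome 3, 89093588 to 89101959), rose by 2.94 ± 0.609 (adjusted p = 0.00131). Kdm6b (0.22, adjusted p = 0.434), Pdpn (0.07, adjusted p = 0.838), Cxcl13 (0.40, adjusted p = 0.314) and Ezh2 (0.25, adjusted p = 0.483) passed no test. Il6 passed none either (1.01, adjusted p = 0.0955), but rose without replicate 12 (2.25, adjusted p = 0.00107) or 8 (1.38, 0.0415).

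At day 23 a total of 9348 genes changed, 2343 higher and 7005 lower, and 3312 with the stricter filter, 1365 higher and 1947 lower. Without replicate 8 or 9 the count was 4061 and 5740. Ryr3, at 14.1 CPM in hour 0, was at least 97.2-fold lower. Heat-shock genes rose in 12 of 12 (12 adjusted over the list alone, camera adjusted p = 5.34e-10, adjusted p = 0.076 with an estimated correlation), with the chaperone gene Hspa1b at 1.89. MHC class I genes rose in 14 of 15 (15 adjusted over the list alone, 4.3e-13, adjusted p = 0.0842 with an estimated correlation). MHC class II genes rose in 6 of 7 (6 adjusted over the list alone, 1.24e-07, adjusted p = 0.0815 with an estimated correlation). Complement genes rose in 9 of 11 (9 adjusted over the list alone, 1.23e-06, adjusted p = 0.0725 with an estimated correlation). Cholesterol synthesis genes rose in 7 of 16 (7 adjusted over the list alone, 1.27e-06, adjusted p = 0.0988 with an estimated correlation).

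Epithelial genes rose at day 23 in 8 of 14, Krt8 by 2.44 (8 rises and 1 fall adjusted over the list alone, camera adjusted p = 0.000105, adjusted p = 0.192 with an estimated correlation). Secretory genes had 12 rises and 2 falls among 21 (12 and 5 adjusted over the list alone, 0.00107, adjusted p = 0.362 with an estimated correlation). Macrophage, monocyte and dendritic genes had 4 rises, Lyz2 by 2.14, and 1 fall among 14 (5 and 1 adjusted over the list alone, 0.00164, adjusted p = 0.172 with an estimated correlation). T and NK cell genes rose in 3 of 14 (2 adjusted over the list alone, 0.013, adjusted p = 0.168 with an estimated correlation). The last 2 calls ended with the stricter filter (0.0681 and 0.803) and with only the 2 groups compared (0.058 and 0.357).

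Interferon-gamma-responsive genes, at day 23, rose in 17 of 20 and fell in 1 (17 and 1 adjusted over the list alone, camera adjusted p = 9.87e-12, adjusted p = 0.121 with an estimated correlation). Type I interferon-stimulated genes rose in 9 of 26 and fell in 2 (9 and 2 adjusted over the list alone, 7.35e-05, adjusted p = 0.309 with an estimated correlation). Inflammatory genes rose in 8 of 27 and fell in 3 (9 and 4 adjusted over the list alone, 0.000477, adjusted p = 0.365 with an estimated correlation). With the stricter filter these last 2 calls ended (0.0533 and 0.0856). Immediate-early genes rose in 8 of 20 and fell in 1 (10 and 2 adjusted over the list alone, 0.000125, adjusted p = 0.353 with an estimated correlation). Glycolysis genes rose in 6 of 15 (6 adjusted over the list alone, 0.000307, adjusted p = 0.172 with an estimated correlation). H3K27 methylation writers and erasers rose in 3 of 12 (3 adjusted over the list alone, 0.000745, adjusted p = 0.0842 with an estimated correlation). The H3K27 call ended with the stricter filter (0.0582) and with only the 2 groups compared (0.0522). Resting fibroblast genes rose in 5 of 20 and fell in 1 (5 and 1 adjusted over the list alone, 0.00963, adjusted p = 0.365 with an estimated correlation). Extracellular matrix genes were called up with 1 rise and 1 fall among 24 (1 and 1 adjusted over the list alone, 0.0143, adjusted p = 0.546 with an estimated correlation). Lymphoid stromal genes were called up with 3 rises and 3 falls among 21 (3 and 3 adjusted over the list alone, 0.038, adjusted p = 0.176 with an estimated correlation). The calls of these last 3 lists ended with the stricter filter (0.478, 0.723 and 0.214), with only the 2 groups compared (0.349, 0.553 and 0.145) and with library totals (0.0689, 0.27 and 0.0724), among other settings. Under library totals 6 medians turned: type I interferon from 0.26 to -0.18, glycolysis from 0.23 to -0.21, H3K27 from 0.33 to -0.11, resting fibroblast from 0.22 to -0.24, matrix from 0.17 to -0.29 and lymphoid stromal from 0.14 to -0.28. No list was called down, but some had mostly falls. Glial genes had 1 rise and 5 falls among 8 (camera adjusted p = 0.0868) and lymphatic endothelial genes 0 and 4 among 6 (0.189). With the stricter filter both were called down (0.00466 and 0.0235). Contractile genes had 0 rises and 6 falls among 12 (0.333, and 0.05 with the stricter filter).

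**Figure D3:**
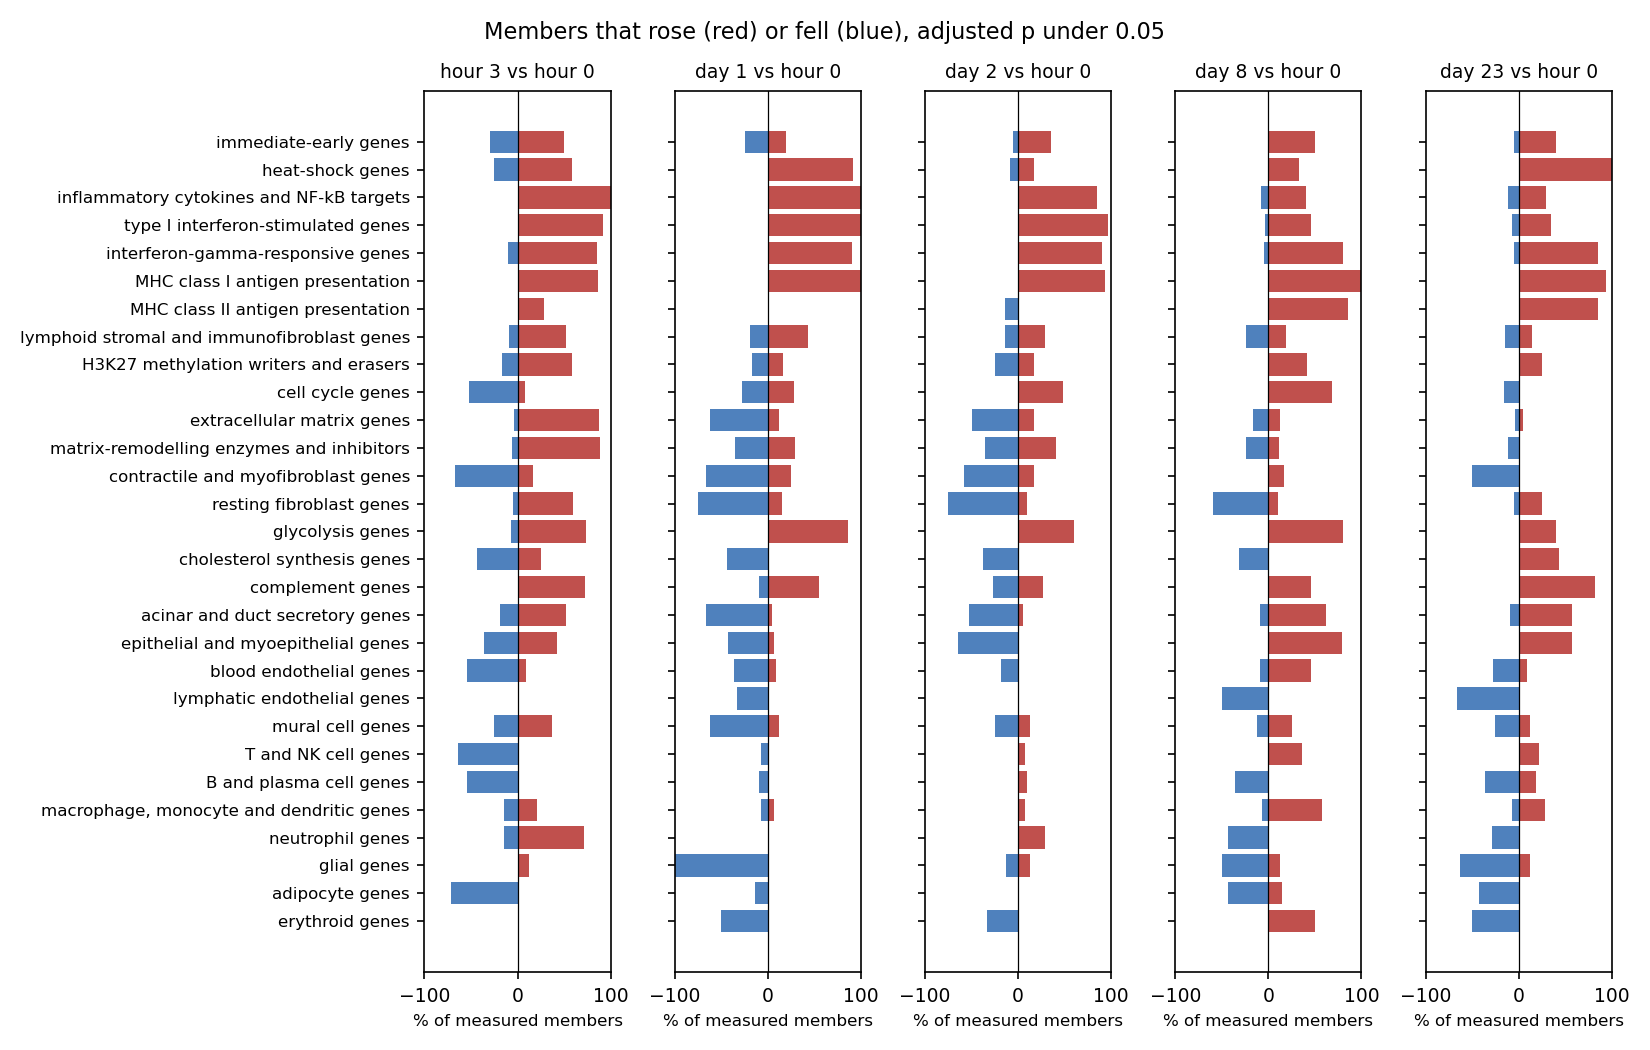
Percent of measured members of each list that rose (red, right of 0) or fell (blue, left of 0) against hour 0 at 5 time points under TMM scaling. Inflammatory genes rose in 27 of 27 members at hour 3 and at day 1, and resting fibroblast genes fell in 15 of 20 at day 1 and at day 2 after 12 rises at hour 3 that became 1 rise and 9 falls under library totals.

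Il6 fell by 6.00 from hour 3 to day 1 (adjusted p = 5.12e-10), Kdm6b by 3.36 (adjusted p = 1.25e-12) and Pdgfra by 3.80, while Cxcl13 rose by 4.04 (adjusted p = 2.41e-11). The steps between infected time points ask when each response turned. Pdpn fell by 1.29 over the first of them, but with library totals its change was -0.02 (adjusted p = 0.939). The GTPase gene Gbp10 rose by 6.97, the growth factor gene Alkal2 fell by 8.75 and Psrc1, a spindle protein gene, was higher at a ratio of 352 (62.9 to 13900). In this step, which crosses the sets, 12198 genes changed, 7574 higher and 4624 lower. With library totals 17166 were higher and 1531 lower, and 768 of the genes called both ways had the opposite sign.

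From day 1 to day 2, within a set, Pdgfra rose by 1.21 (adjusted p = 1.79e-05), Ezh2 by 1.11 (adjusted p = 0.00493) and the kinase gene Aatk by 5.98, while Cxcl13 fell by 2.44 (adjusted p = 1.16e-06) and Coch, a matrix protein gene, by 3.69. Il6 rose by 1.26 (adjusted p = 0.045), a call that ended with DESeq2 (0.0803) and without any 1 of replicates 13 to 17 (highest 0.198, without replicate 16). Over this step estimated background rose from 1.66% to 10.2% of counts, and genes outside the stricter filter had a median log2 fold change of 1.736. Of the genes called past 2-fold, 2988 were higher and 909 lower. How far background accounts for the higher calls was not tested. In all 6388 genes changed, 51.8% of them higher. Under the settings fixed beforehand this share ran from 34.3% (no filter) to 74.5% (limma-voom), with 71.0% for DESeq2 size factors, and it was 42.2% in a fit of only the set of hour 0, day 1 and day 2, so neither direction held the majority throughout. Leaving out replicate 13, 15, 16, 17 or 18 gave 3968, 3945, 3957, 3490 and 3977 genes, and subtraction of estimated background 3502. From day 2 to day 8, across the sets, 16898 genes changed, 29.4% of them higher, or 18.5% with size factors and 48.9% with the stricter filter. Scgb1b27 rose by 10.24, Scgb2b27 by 9.63 and the kallikrein Klk1 by 9.55 (each with paralogs), Pdgfra by 1.55 (adjusted p = 7.76e-08), Cxcl13 fell by 3.22 and Il6 by 3.24. The largest falls, of Xirp2, Lrp1b, Myh13 and Dnah6, were to 0 counts from 16.0 CPM or less, with Xirp2 at least 198-fold lower.

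C7, a terminal complement component gene, rose by 3.88 ± 0.544 from day 8 to day 23 (adjusted p = 6.76e-05), and the cell division gene Aspm fell by 4.09. This step, within a set, asks which changes of the first week subsided. Fdps rose by 3.25, a call that ended after subtraction of estimated background (adjusted p = 0.0614), the membrane protein gene Palm3 by 2.98 and the secreted Angptl1 by 2.92. The alpha-globin gene Hba-a2 was at least 90.2-fold lower and the iron-binding Ltf lower at a ratio of 227 (40.5 to 8990). In all 1465 genes changed, 618 higher and 847 lower, and 593 and 808 did without replicate 2 or 3.

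Cell cycle genes fell in 19 of 25 between day 8 and day 23 (22 adjusted over the list alone, camera adjusted p = 7.05e-31, adjusted p = 0.000124 with an estimated correlation). Epithelial genes fell in 12 of 14 (13 adjusted over the list alone, 1.11e-13, adjusted p = 0.0476 with an estimated correlation). Erythroid genes fell in 4 of 6 (5 adjusted over the list alone, 2.94e-10, adjusted p = 0.0128 with an estimated correlation). Cholesterol synthesis genes rose in 9 of 16 (12 adjusted over the list alone, 9.18e-17, adjusted p = 0.0223 with an estimated correlation). Resting fibroblast genes rose in 10 of 20 (14 adjusted over the list alone, 2.29e-11, adjusted p = 0.0588 with an estimated correlation).

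Between day 8 and day 23 contractile genes fell in 4 of 12 (8 adjusted over the list alone, camera adjusted p = 4.34e-07, adjusted p = 0.117 with an estimated correlation). Macrophage, monocyte and dendritic genes fell in 3 of 14 (6 adjusted over the list alone, 2.22e-05, adjusted p = 0.0842 with an estimated correlation). Blood endothelial genes fell in 3 of 11 (4 adjusted over the list alone, 0.000135, adjusted p = 0.157 with an estimated correlation). Glial genes fell in 2 of 8 (4 adjusted over the list alone, 0.00102, adjusted p = 0.0755 with an estimated correlation). Glycolysis genes fell in 3 of 15 (8 adjusted over the list alone, 0.000275, adjusted p = 0.172 with an estimated correlation). Secretory genes fell in 3 of 21 and rose in 1 (5 and 1 adjusted over the list alone, 0.00125, adjusted p = 0.365 with an estimated correlation). Without replicate 7 the secretory call ended (0.205). Heat-shock genes rose in 6 of 12 (7 adjusted over the list alone, 2.57e-07, adjusted p = 0.117 with an estimated correlation). T and NK cell genes were called down with no member of 14 passing (0 adjusted over the list alone, 0.0295, adjusted p = 0.207 with an estimated correlation). Immediate-early genes fell in 3 of 20 (6 adjusted over the list alone, 0.0332, adjusted p = 0.591 with an estimated correlation). Type I interferon-stimulated genes fell in 4 of 26 and rose in 1 (6 and 1 adjusted over the list alone, 0.0184, adjusted p = 0.546 with an estimated correlation). MHC class II genes fell in 1 of 7 (2 adjusted over the list alone, 0.0301, adjusted p = 0.414 with an estimated correlation). These last 4 calls ended with the stricter filter (0.358, 0.116, 0.073 and 0.105), without replicate 1 (0.113, 0.21, 0.406 and 0.0734) and without the day 2 libraries (0.0686, 0.0586, 0.0586 and 0.0658), among other settings.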

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

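Of the tests in this part, only the slope over the exon length of receptor genes was written down before its result, and the others, the tests of differences between time points included, were chosen after the values they address had been seen.

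Extracellular matrix genes moved apart between hour 3 and day 1, with median log2 changes of 1.12 and -1.02 against hour 0 (adjusted p of the difference = 3.61e-16 over 290 tests of lists), although the hour 3 median was -0.06 under library totals. Resting fibroblast genes differed between the same times (0.58 and -2.13, 4.81e-11), with -0.59 at hour 3 under library totals. Cholesterol synthesis genes were lower at day 1 and higher at day 23 (-0.78 and 0.67, 1.01e-10). Secretory genes were lower at day 1 and higher at day 8 (-3.46, or -2.98 at the bound, and 2.33, 2.09e-12), and epithelial genes lower at day 2 and higher at day 8 (-1.63 and 2.42, 2.09e-12). Ezh2 was lower at day 1 and higher at day 8 (-0.95 and 0.82, 9.13e-06), and each of these 2 calls ended under some other settings. With an estimated correlation none of the list calls behind these pairs held (adjusted p = 0.144 and 0.382 for matrix, 0.172 and 0.168 for resting fibroblast, 0.318 and 0.0988 for cholesterol, 0.309 and 0.187 for secretory, 0.0957 and 0.0588 for epithelial genes). What singled these out is opposite calls at 2 times with a difference that passed its own test. Each of these differences spans the sets of libraries. Receptor genes, used as a measure of background although 506 of the 1499 passed the filter and were tested with all genes, had 3.24 counts per kb per 10M nuclear counts at day 2, above the 1.42 of the uninfected group.

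Genes of low abundance were lower at hour 3, day 8 and day 23 than at hour 0. Deeper sequencing of the hour 0, day 1 and day 2 libraries is argued against by detection at equal depth, where the lowest of these 9 libraries had 25288 genes and the highest of the others 19327. Over 1499 receptor genes, counts in these libraries grew with exon length at a log-log slope of 0.809 (95% interval 0.712 to 0.906). Reads spread over the genome, such as genomic DNA or unspliced RNA, may give such a rise. Counts of true transcripts at a low level may grow with exon length too, so the slope cannot tell these apart. It lies under the slope of 1 of an exactly even spread, and no slope was taken in the other 9 libraries. After subtraction of the receptor-gene rate 13020 of the 16503 genes at hour 3 and 5155 of the 9348 at day 23 were still called. The other subtraction left 10119 and 2541, but its rates come from genes chosen for being almost absent at hour 3, day 8 and day 23, so part of that loss follows from the choice and it does not test the explanation. The sets follow the replicate numbers (1 to 9 and 10 to 18) and not the order of time, since hour 3 lies between hour 0 and day 1. The labels give no batch. Whether the sets were prepared apart, or the cells differed in low-level transcription by time, was not tested.

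Secretory transcripts were low at day 1 and day 2. A lower share of epithelial cells of every kind would lower both epithelial and secretory lists. Their medians differed by 2.73 (SE 0.826) at day 1, or 2.25 (SE 0.935) with the member at 0 counts at its bound. For these members that argues against it at day 1, but at day 2 the difference was 0.87 (SE 0.984), and it may hold. These SEs come from resampling list members and do not cover variation between mice. Estimated background was 1.66% of counts at day 1 and 10.2% at day 2, where it may hide falls of weakly counted members. The difference of the medians was not taken again after subtraction. Less RNA from 1 secretory source in fixed proportions is argued against at day 2 for the 6 members of the secretory list most abundant at hour 0. Of these Lpo lay 4.7 SE from the common change of -5.11, and 4.2 SE from -5.49 after subtraction. Klk1 lay 4.06 and 3.55 SE away. The list holds acinar and duct genes together, so this does not bear on a fixed-proportion loss within each source. These distances take the genes as independent, though they share libraries. Car6 and Prol1, the most abundant of the list at hour 0, were at -5.91 and -6.81, and Mucl2, outside the list and more abundant, at -6.59. A loss of secretory gene expression, or of secretory cells in particular, may remain, as may carry-over of acinar RNA that varies with dissociation, which the gp38 sort would largely exclude as whole cells, and none of these last was tested.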

How the results depend on the processing

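Scaling by library totals, the fits without day 2 or with only 1 set of 9 libraries, and both subtractions of background were chosen after seeing the data. Of 544 results for named genes 506 were called, and 397 kept their call under every setting fixed beforehand, while 109 lost it at least once. Of 174 list results 94 were called and 15 kept the call. Every total of called genes stayed within 1.5 times its value with DESeq2 size factors, no filter and DESeq2, but the split by direction did not: from day 1 to day 2 the 3076 lower became 1675, 4870 and 1901. The stricter filter, which tests fewer genes, left 9329 changed at hour 3, 4851 at day 8, 3312 at day 23, 6931 from day 2 to day 8 and 12685 over the 6 groups. With limma-voom 6427 changed at day 2 and 13496 from day 1 to day 2. With only the 2 groups compared, which has fewer samples and filters the genes anew, 7182 changed at day 8, 1997 at day 23 and 708 from day 8 to day 23. Subtraction of estimated background gave 10372 at hour 3, 5539 at day 8, 2627 at day 23, 3502 from day 1 to day 2, 9852 from day 2 to day 8 and 963 from day 8 to day 23, and the receptor-gene subtraction 5206 at day 23. Without the day 2 libraries 6783 changed at day 8 and 5123 at day 23, and with library totals 18697 from hour 3 to day 1. The causes of these differences were not tested apart.

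Leaving out 1 replicate gave 12278 to 16396 genes at hour 3, 4811 to 6623 at day 1, 2935 to 3680 at day 2, 7204 to 12486 at day 8 (7954, 7215 and 7204 without replicates 1, 2 and 3) and 4061 to 9166 at day 23 (4061 and 5740 without replicates 8 and 9). It gave 8932 to 11981 from hour 3 to day 1, 3490 to 7745 from day 1 to day 2 (3968, 3945, 3957, 3490 and 3977 without replicates 13, 15, 16, 17 and 18), 15472 to 16692 from day 2 to day 8, 593 to 1678 from day 8 to day 23 (593 and 808 without replicates 2 and 3) and 22847 to 26596 over the 6 groups. Lists called ran from 15 to 18 at hour 3, 13 to 15 at day 1, 12 to 15 at day 2, 17 to 18 at day 8, 16 to 20 at day 23 and 15 to 18 from day 8 to day 23. With an estimated correlation 3 of 15 lists were called at hour 3, 5 of 15 at day 1, 2 of 13 at day 2, 1 of 17 at day 8, 0 of 18 at day 23 and 4 of 16 from day 8 to day 23.

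Direction reversed under library totals for Cdh19 (-0.704), Kdm6a (-1.08) and Pdgfra (-0.784) at hour 3, for Kdm6a (1.11) and Ezh2 (0.658) from hour 3 to day 1 and for Kdm6a (-0.123) and Ezh2 (-0.113) from day 2 to day 8, each where that scaling moves all genes the same way. Pax5 at day 8 reversed after subtraction of estimated background (1.01), and the cause was not tested. No paired analysis was possible because each library has a mouse of its own. In the simulation small changes were mostly missed: of 1.5-fold changes at hour 3 against hour 0, 2.99% were recovered. Far fewer genes changed there than were called in the real contrasts, which makes the adjusted p harder to pass. The share recovered therefore does not carry over to the real contrasts.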

Other observations

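The test of dilution and the regroupings below were written down after the values they address had been seen.

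Some members of the mural and blood endothelial lists passed the gene test. The mural list was called lower at day 1 (camera adjusted p = 0.0184) but not called at hour 3 (0.091), day 2 (0.0931) or day 8 (0.253). Its day 1 call ended with an estimated correlation (0.195) and without replicate 12 or 14 (0.0514 and 0.0624). The blood endothelial list was called higher at day 8 (0.00196), a call that ended with the stricter filter (0.0752) and with an estimated correlation (0.24). Cspg4, a pericyte proteoglycan gene, rose by 2.95 at hour 3 (1732 against 224 CPM, adjusted p = 1.46e-11) and fell by 2.98 at day 1 and by 2.22 at day 2, and by 1.30 at day 8. Rgs5, a pericyte signalling regulator gene, rose by 3.52 at day 8 (adjusted p = 2.28e-06) and Notch3, a mural cell receptor gene, by 2.61 (adjusted p = 3.31e-08). The endothelial adhesion gene Cdh5 rose by 2.60 at day 8 (adjusted p = 0.000169).

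In the contrasts of day 8 and day 23 with hour 0, which cross the sets, Vaultrc5, a vault RNA gene, rose by 6.03 at day 8 and by 5.26 at day 23, and Rnu12, a minor spliceosome RNA gene, by 4.86 and 4.37. Il1b, an inflammatory cytokine gene, was higher at day 8 (4.22, adjusted p = 6.2e-08) and at day 23 (3.37, adjusted p = 7.49e-06). The complement genes C1qb and C1qc, made by macrophages, rose by 3.71 and 3.66 at day 8 and by 2.85 and 2.58 at day 23.

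Cxcl13 fell by 5.66 (SE 0.348) from day 1 to day 8. Dilution of stromal RNA by RNA of other cells would lower other stromal transcripts too, yet extracellular matrix genes had a median change of 1.22, with 15 of 24 rising and 2 falling. The SE of that median, 0.297, comes from resampling list members and not from mice. Lower expression of Cxcl13 per cell or fewer cells that express it may remain, and the step crosses the sets of libraries.

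Regrouping all 18 libraries at random gave as many genes as the 23092 over the 6 groups in 1 of 100 groupings, the real one included, and 621 at most in the others, so chance can be excluded there. The random groupings break up the sets of libraries along with the times, so they do not tell time from set. The 10 splits of 3 against 3 are too few for a share under 0.05. Every other split mixes libraries of both groups, so a real difference adds to the spread and leaves few gene calls. For lists, the mixed splits keep part of the real contrast. The highest other counts therefore do not show how many calls chance would give without a real difference. In each contrast 1 of the 10 splits, the real one, gave as many genes: 16503 at hour 3 (highest other 0), 6193 at day 1 (2), 4061 at day 2 (1), 12076 at day 8 (0), 9348 at day 23 (177), 12198 from hour 3 to day 1 (0), 6388 from day 1 to day 2 (1), 16898 from day 2 to day 8 (0) and 1465 from day 8 to day 23 (9). As many lists as the 15 at hour 3 were called in 4 of 10 splits (highest other 18), and as many as the 17 at day 8 in 3 of 10 (highest other 18). The count of lists was reached in 1 of 10 splits at day 1 (15, highest other 10), day 2 (13, highest other 11), day 23 (18, highest other 16) and from day 8 to day 23 (16, highest other 15).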
